A study of Homo sapiens with 18 samples.

How the data were processed

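The series holds 18 RNA-seq libraries of RPE1 clones, 3 biological replicates (A, B and C) of each of 6 clones, in 3 pairs of 1 tetraploid and 1 diploid clone. Per the labels, RNA was extracted on a Maxwell instrument, libraries were made from polyadenylated RNA with a stranded TruSeq kit, reads were demultiplexed with CASAVA 1.8.2 and aligned with TopHat2 to hg19, and edgeR was among the tools of the authors. The deposited table holds 1 RPKM value per gene and library for 57773 Ensembl genes, computed by the authors as reads per M reads of the library (M, mega) and per kilobase of gene. The annotation release and the use of the strand in counting are not stated.

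The deposited values were tested for what they hold. For 13502 of 15700 genes with over 50 reads (86%), the length that the RPKM values imply lay within 0.5% of the genomic span of the gene, introns included, so that the RPKM of a gene with long introns is low for its number of reads. The values of a library above 0 are whole multiples of a step for each gene, and 99.9968% came out as whole reads within 0.01 reads; 57641 genes gave whole reads directly, of which 40721 were above 0 in any library, 131 through the gene length within 0.05 reads, and 1 gave none. The divisors of the libraries so implied, in M reads, were 43.8, 41.5 and 36.9 for A, B and C of 2N-1, 42.2, 47.7 and 44.9 of 4N-1, 49.6, 54.8 and 45.3 of 2N-2, 39.5, 39.8 and 44.6 of 4N-2, 36.1, 42.7 and 43.9 of 2N-3, and 37.9, 43.6 and 42.6 of 4N-3. They are not totals of reads, since 9 of 18 libraries held more reads in genes than the divisor (0.956 to 1.04 times it over all libraries), and were used as effective library sizes; how the authors scaled them is not stated. Symbols, chromosomes, gene order and transcript features came from GENCODE v29 (GRCh38), which matched 52338 genes by identifier; positions printed are of that build, not of hg19, and unmatched genes are given by identifier.

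Choices were fixed before the data were examined except where stated. Genes with 1 RPKM or more in 3 or more libraries were tested (9704). The values log2(RPKM + 0.5) were fitted with limma 3.58.1 in R 4.3.3 (a mean for each of the 6 clones, moderated with a trend in the spread), and the tetraploid clone was compared with the diploid clone of each pair, with two-sided tests and Benjamini-Hochberg adjustment over all tested genes. A gene was called at an adjusted p below 0.05 and a change of 2-fold or more. All 18 libraries share 1 estimate of the spread, and the replicates are libraries of a clone, so that a pair test is about those 2 clones. Genes called in all 3 pairs were the calls shared with the same sign, beside the number expected from independent lists. Across clones, the mean of each clone was fitted with the pair as a block, 3 against 3. Differences between pairs were tested with a moderated F test, with a span of 2-fold or more between pairs.

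Lists of genes, 20 in all, were tested with camera at the preset correlation of 0.01 and with an estimated correlation, adjusted over lists and comparisons; members were also adjusted over the list alone. The lists were p53 targets, G1 cyclins with CDKs and CDK inhibitors, mitosis genes, DNA replication and S phase genes, centrosome and centriole genes, Hippo (YAP/TAZ) targets, secreted factors of senescent cells, interferon-stimulated genes, cholesterol synthesis and uptake, unfolded protein response, glycolysis, lysosome genes, proteasome subunits, cytosolic ribosomal proteins, fibrillar matrix and matrix enzymes, epithelial-mesenchymal regulators and markers, keratins and cell junction genes, actin cytoskeleton and focal adhesion, retinal pigment epithelium markers, and markers of other cell types. Chromosomes were tested with camera as sets of genes in each pair and called at an adjusted p below 0.05 and an offset of 0.1 or more from the other genes. The chromosome profiles used recovered reads of genes with a mean of 300 reads or more, in windows of 40 genes.

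Chosen after seeing the data, because CCND2 and other genes of long span missed the RPKM minimum, the recovered reads were fitted with limma-voom on genes with 10 or more reads in 3 or more libraries (23396), with the divisors above as library sizes, and across clones on reads summed per clone. Values in reads per M are recovered reads over the implied divisor. Ratios of reads carry 95% exact binomial intervals. Where a clone had 0 reads the fold is a lower bound against a floor of 3 reads over its 3 libraries, and where it had 1 to 3 reads the ratio is given with its interval; both cover counting error only.

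Named genes followed a rule: the 10 called genes with the largest rise and the 10 with the largest fall in each pair, among those whose libraries did not overlap between the clones and whose higher mean was 2 RPKM or more (100 reads in the analysis of reads); up to 15 per direction called in all 3 pairs; up to 10 per direction across clones; CCND1, CCND2, CCND3, CDK4, CDK6, CDKN1A, MDM2 and AURKB in every comparison; up to 4 members of each list with the largest mean change and any called in all 3 pairs; the 10 with the widest difference between pairs; and genes needed to describe a called chromosome. The text names part of these, and some genes that the rule picks are not reported here.

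Alternatives were a pseudocount of 0.1 or 1, no filter, a mean of 5 RPKM or more, median-of-ratios scaling, quantile normalization, no minimum fold, only the 6 libraries of a pair, no pair block, the correlation within a clone, each pair and each of the 18 libraries left out, and a block of libraries that share pair and letter (9 blocks). The analysis of reads, the omission of libraries A of 2N-3 and C of 4N-3 (both doubted from their position among the samples), and the analysis of reads with that block were added after seeing the data. Changes of A, B and C followed each other weakly across the clones of pairs 1 and 2. Correlations across genes were 0.05 to 0.12 in pair 1 for the same letter, and -0.12 to 0.03 for different letters. In pair 2 they were -0.02 to 0.22 and -0.21 to 0.08. In pair 3 the same letter (-0.12 to 0.03) did not stand out from different letters (-0.12 to 0.16). Letters were read as names in the main fit, with the block as an alternative. The whole procedure was tested on simulated data with known changes. Of 3-fold changes, 86.6%, 80.6% and 82.1% were called in pairs 1, 2 and 3 on RPKM, and 83.6% across clones. Outside the 200 genes so changed, 0, 1 and 0 were called in the pairs on RPKM and 6, 29 and 7 on reads. Those counts also cover chromosome 1 genes in pair 2 and lysosome genes in pair 3, which were shifted by -0.4 and 0.5. Every simulated tetraploid clone had the same change, with library noise alone (log2 SD 0.12) and no variation between clones. The 83.6% is therefore not the power to find a change across the real clones. No library was left out of the values reported, and no sequence reads were at hand, so alignment and counting were not repeated.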

Results

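Messenger RNA was measured in RPE1, an immortalised human line of retinal pigment epithelium, in 6 clones that had survived the same drug treatment. Per the labels, the cells were kept for 72 h in 2.5 uM ZM447439, an inhibitor of the Aurora kinases that lets cells leave mitosis without dividing, and single cells were cloned after some weeks of growth. Each tetraploid clone (4N) was paired with a diploid clone (2N) taken from the same plates, which made 3 pairs: 4N-1 with 2N-1, 4N-2 with 2N-2 and 4N-3 with 2N-3. Both clones of pair 2 were stained with a Hoechst dye before they were cloned again. Every clone had 3 libraries (A, B and C), 18 in all, with 37.1 to 54.3 M reads (M, mega) in genes per library, as recovered from the deposited values. Between 30422 and 32408 of the 57773 listed genes were above 0. Each pair asks which transcripts differ between a tetraploid clone and a diploid clone of the same origin, and the 3 pairs together ask which differences recur. Levels are means with their SD over 3 libraries per clone (n = 3), and changes are log2 values of 4N over 2N with the standard error (SE) of the fit. The pair tests compare libraries of 2 clones. A gene is said to have risen or fallen where its Benjamini-Hochberg adjusted p passed 0.05 in limma. It is called where it also changed 2-fold or more.

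**Figure D1:**
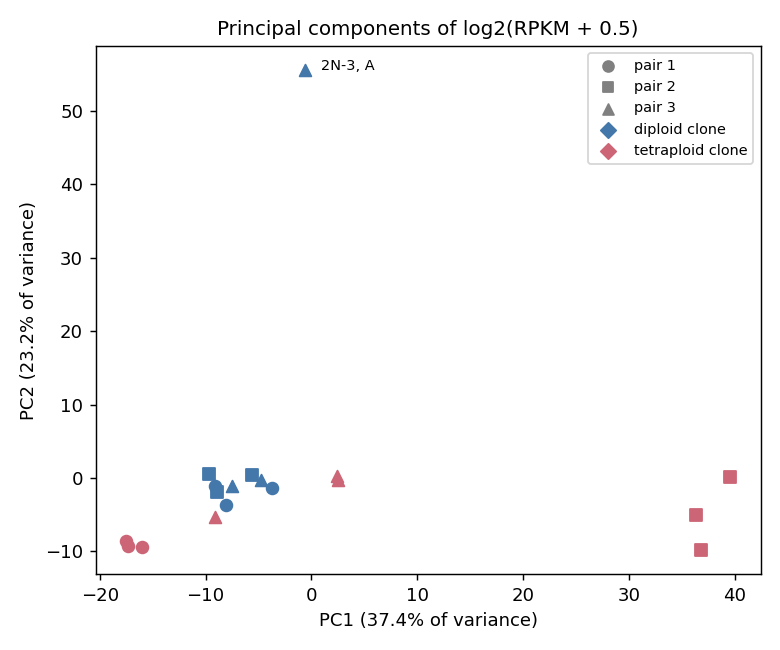
Principal components 1 (37.4% of the variance) and 2 (23.2%) of log2(RPKM + 0.5), 1 mark per library, coloured by ploidy (diploid or tetraploid clone) and shaped by pair. The 3 libraries of 4N-2 lie apart at 36.4 to 39.6 on component 1, and library A of 2N-3 lies apart at 55.6 on component 2.

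The clearest separation among the 6 clones was that of 4N-2, whose 3 libraries lay at 36.4 to 39.6 on the first principal component, against -17.5 to 2.56 for the other 15. One library, A of 2N-3, lay at 55.6 on the second component, and the other 17 lay between -9.83 and 0.54. Library C of 4N-3 had lower levels of mitosis and S phase genes than libraries A and B of that clone, by a median log2 difference of -0.76 over 67 genes, all of which were lower. Both libraries belong to pair 3, and values of that pair that move with them are given with the genes they touch.

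Transcripts of CCND2, which encodes the cell-cycle activator cyclin D2, were close to absent in the diploid clones and far higher in all 3 tetraploid clones. The gene (ENSG00000118971, chromosome 12, 4273772 to 4305350 in GRCh38) went from 0.0654 ± 0.0272 (SD, n = 3) reads per M in 2N-1 to 18.8 ± 0.789 in 4N-1. It went from 0.0128 ± 0.0111 to 21.7 ± 2.90 in pair 2 and from 0.492 ± 0.137 to 10.9 ± 1.37 in pair 3. The read totals were 8 against 2540 in pair 1, a ratio of 288 with a counting interval of 146 to 668. They were 2 against 2673 in pair 2, a ratio of 1615 (447 to 13344), and 60 against 1355 in pair 3, a ratio of 22.3 (17.2 to 29.4). Such intervals, and the lower bounds below, cover counting error only. The study is known to have reported on CCND2 in these libraries, so this change is not independent evidence. CCND2-AS1, a transcript that overlaps CCND2 on the chromosome, was at 0 reads in 2N-1 and 2N-2, and was at least 121-fold higher in 4N-1 and at least 55.2-fold higher in 4N-2, with a rise of 3.96 (SE 0.46) in pair 3. Whether reads were counted by strand is not stated, so reads of the overlap may belong to either gene. Of the other D-type cyclins, CCND1 rose in pair 1 (0.47, SE 0.15, adjusted p = 0.0352) and in pair 2 (0.86, SE 0.15, adjusted p = 2.95e-04) and had a change of 0.47 in pair 3 that did not pass (adjusted p = 0.106). CCND3 rose in pair 2 (0.80, SE 0.14, adjusted p = 1.79e-04), with changes of -0.03 in pair 1 and 0.21 in pair 3 that did not pass. Their kinase partners CDK4 and CDK6 passed in no pair, with changes between -0.41 and 0.32. CCND2, CCND2-AS1, CCND3 and CDK6 did not reach the minimum of 1 RPKM in 3 libraries, because the deposited lengths include introns. Their values come from whole reads recovered from the deposited values, an analysis chosen after seeing the data.

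**Figure D2:**
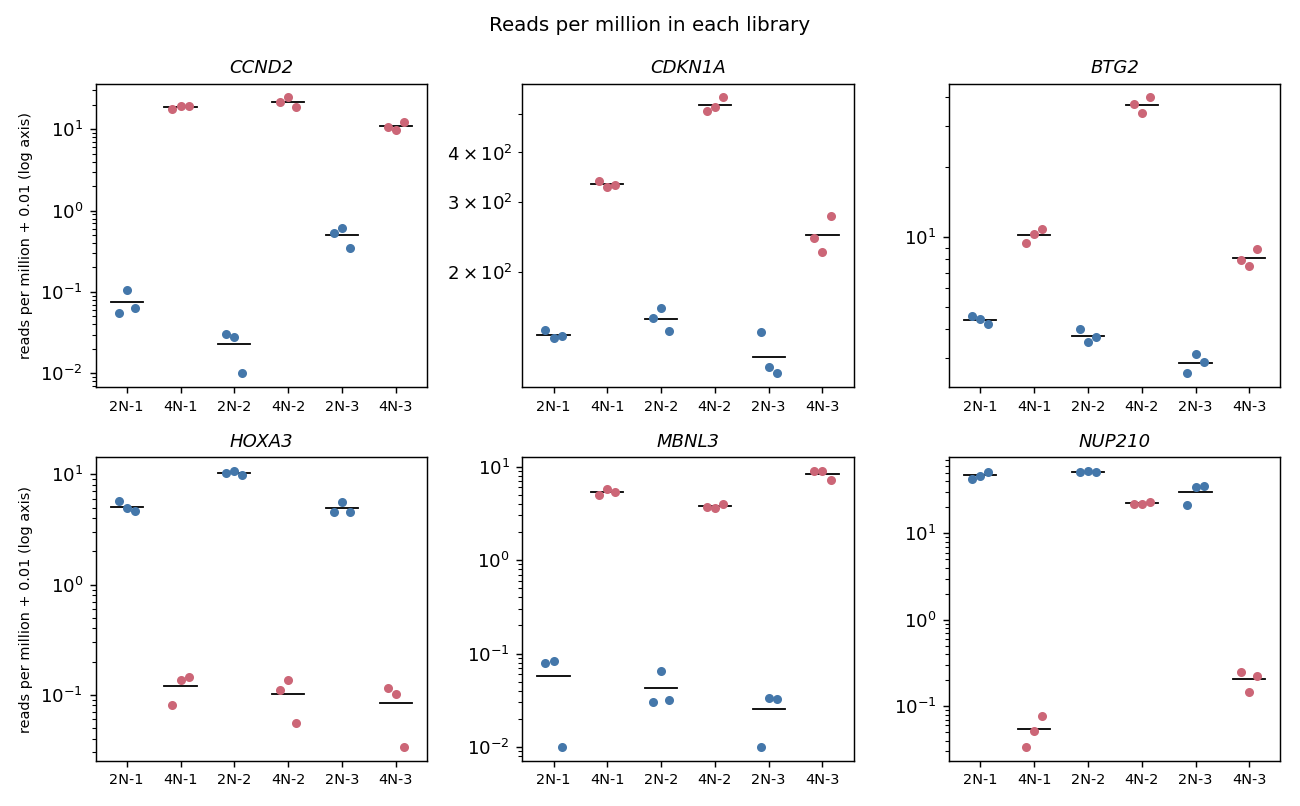
Reads per M (plus 0.01, log axis) of CCND2, CDKN1A, BTG2, HOXA3, MBNL3 and NUP210 in the 6 clones; each dot is a library and each line the mean of 3. CCND2 lies at 0.0128 to 0.492 reads per M on average in the diploid clones and at 10.9 to 21.7 in the tetraploid clones.

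Of the list of 18 G1 cyclins, CDKs and CDK inhibitors, 11 had levels high enough to test. Of these, 3 rose and 4 fell in pair 1, 4 rose and 2 fell in pair 2, and 1 rose and none fell in pair 3. Adjusted over the list alone, 5 rose and 6 fell, then 4 rose and 2 fell, then 3 rose and 1 fell. The inhibitor CDKN2C fell by 0.89 (SE 0.10) in pair 1. As a group the list passed in no pair (adjusted p = 0.770, 0.780 and 0.134), nor across clones (adjusted p = 0.512), where its median was -0.03 and its mean 0.11. On recovered reads, with all 18 members tested, it passed as higher in pair 3 (adjusted p = 0.0464, and 0.238 with an estimated correlation), where 2 rose and 1 fell (4 and 2 adjusted over the list alone).

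Genes of the list of p53 targets rose in all 3 pairs. CDKN1A, which encodes the CDK inhibitor p21 (ENSG00000124762, chromosome 6, 36676460 to 36687339), went from 12.8 ± 0.336 to 30.8 ± 0.561 RPKM in pair 1 (1.23, SE 0.09, adjusted p = 9.18e-07). It went from 14.1 ± 0.957 to 48.7 ± 2.02 in pair 2 (1.75, SE 0.09, adjusted p = 3.35e-09) and from 11.3 ± 1.5 to 23.0 ± 2.47 in pair 3 (0.99, SE 0.09, adjusted p = 2.59e-05). The antiproliferative gene BTG2 rose by 0.92, 2.76 and 1.05. MDM2, which encodes a ubiquitin ligase, rose by 0.38, 1.13 and 0.69. EDA2R, a receptor of the TNF family, rose by 0.74, 1.14 and 0.76, and AEN, a nuclease gene, by 0.37, 1.61 and 0.67. SPATA18 rose in the analysis of reads by 2.25 (SE 0.14), 4.27 (SE 0.16) and 1.61 (SE 0.14). Of the 26 members tested, 17 rose in pair 1, 23 in pair 2 and 12 in pair 3, and none fell. Adjusted over the list alone, 20, 25 and 15 rose. The median change was 0.38, 0.95 and 0.30. The group passed in each pair with the preset correlation between genes (camera, adjusted p = 1.37e-12, 8.42e-15 and 1.26e-12) and with an estimated one (adjusted p = 0.00149 in each). In pair 3 the 2-fold call of BTG2 ended without library C of 4N-3 (0.99) and without both doubted libraries, A of 2N-3 and C of 4N-3 (0.95). CDKN1A in pair 3 reached 2-fold without library A of 2N-3 (1.09), A of 4N-3 (1.00) or B of 4N-3 (1.06).

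In pair 1, single genes of smooth muscle and matrix rose in 4N-1, and most genes of the mitosis and S phase lists fell. LUM, which encodes the matrix proteoglycan lumican, went from 2.73 ± 0.167 to 13.8 ± 0.782 RPKM (2.14, SE 0.14, adjusted p = 2.81e-07). The smooth muscle genes TAGLN (17.4 ± 0.808 to 72.9 ± 2.39 RPKM), MYL9 (11.8 ± 0.223 to 48.4 ± 0.136 RPKM) and ACTA2 (0.620 ± 0.0497 to 3.08 ± 0.0318 RPKM) rose by 2.04, 1.99 and 1.68. ANKRD1, a target of the YAP and TAZ coactivators, went from 40.9 ± 3.58 to 140 ± 2.95 RPKM (1.76, SE 0.13). PCDHB5, a protocadherin, rose by 2.15 (SE 0.11), MAGEH1 by 1.97 (SE 0.13) and the immediate early gene FOSB by 2.02 (SE 0.13). Of the 31 mitosis genes tested 30 fell and none rose, with a median of -1.06. Among them KIF20A, a kinesin of late mitosis, fell by 1.40 (SE 0.13), the cyclin gene CCNB1 by 1.34 (SE 0.14), and the transcription factor gene FOXM1 by 1.30 (SE 0.14). The mitotic kinase gene PLK1 fell by 1.28 (SE 0.16) and AURKB, which encodes a target of the drug, by 1.25 (SE 0.21). The proliferation marker MKI67, outside the list, fell by 1.32 (SE 0.26). Of the 25 S phase genes 24 fell, with a median of -0.82, such as the replication helicase gene MCM7 (21.2 ± 1.90 to 9.73 ± 0.0298 RPKM). All 31 mitosis genes and 24 S phase genes fell when adjusted over the list alone. Both groups passed with the preset correlation (adjusted p = 5.34e-25 and 2.63e-13). Neither call held, at adjusted p = 0.207 and 0.330 with an estimated correlation. Of 9 centrosome genes 5 fell (5 adjusted over the list alone; adjusted p = 0.00669, and 0.330 with an estimated correlation). In all, 141 genes were called of 9704 tested, 63 higher and 78 lower in 4N-1. At any fold 1031 rose and 996 fell. On recovered reads, where 23396 genes could be tested, 537 were called higher and 627 lower. Among these the pore protein gene NUP210 went from 46.7 ± 4.45 to 0.0442 ± 0.0217 reads per M and the pigment cell receptor gene GPR143 from 30.3 ± 1.27 to 0.0377 ± 0.0358. The sugar transporter gene SLC2A10 was at 0 reads in 2N-1 and at least 213-fold higher in 4N-1. HSPB7, a small heat shock protein gene, rose by 7.35 (SE 0.54).

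Several further lists passed as higher in 4N-1 with the preset correlation, most of them not with an estimated one. Of 22 matrix genes tested on RPKM 15 rose and none fell (17 adjusted over the list alone, median 0.54), and the group passed at adjusted p = 1.60e-11, but not at adjusted p = 0.207 with an estimated correlation. Of 25 actin and adhesion genes 15 rose and 1 fell (17 and 1 adjusted over the list alone; adjusted p = 1.29e-07, and 0.0911 with an estimated correlation). Of 10 secreted factors of senescent cells 7 rose and none fell (7 adjusted over the list alone), such as the cytokine gene IL1B (0.91, SE 0.10). This group passed at adjusted p = 1.29e-07, and at adjusted p = 0.00149 with an estimated correlation. CCL2, a chemokine of that list, was listed at 0 in 2N-1 and at 0.940 ± 0.110 RPKM in 4N-1. Of 8 genes of the epithelial-mesenchymal list 4 rose (4 rose and 1 fell adjusted over the list alone; adjusted p = 8.27e-04, and 0.0468 with an estimated correlation). On recovered reads, with 19 members tested, that call was lost (adjusted p = 0.109). Of 17 Hippo targets 8 rose and 3 fell (9 and 3 adjusted over the list alone; adjusted p = 0.00122, and 0.330 with an estimated correlation). Of 18 genes of the unfolded protein response 5 rose (5 adjusted over the list alone; adjusted p = 8.27e-04, and 0.330 with an estimated correlation), such as XBP1 at 0.89 (SE 0.08). Of 10 keratin and junction genes 5 rose (6 adjusted over the list alone), such as KRT18 at 0.72 (SE 0.15). That call, at adjusted p = 0.0325, was at adjusted p = 0.208 with an estimated correlation, 0.0545 without library C of 4N-1 and 0.0518 without library A of 2N-3.

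In pair 2, most genes of the cholesterol synthesis and uptake list fell in 4N-2, and single genes of other functions rose or fell. HMGCS1, which encodes an early enzyme of cholesterol synthesis, went from 13.3 ± 0.717 to 2.41 ± 0.0533 RPKM (-2.24, SE 0.12, adjusted p = 3.63e-09), and INSIG1, a sterol sensor gene, from 26.7 ± 1.38 to 5.52 ± 0.240 (-2.18, SE 0.12). SQLE, an enzyme gene of the same path, fell by 0.91, 1.20 and 0.43 in the 3 pairs. SCD, which encodes a fatty acid desaturase, went from 134 ± 15.4 to 23.5 ± 1.43 RPKM (-2.48, SE 0.20). Of the 24 cholesterol genes 22 fell and none rose in pair 2 (22 adjusted over the list alone, median -1.12). The group passed at adjusted p = 1.07e-17, and at adjusted p = 0.0468 with an estimated correlation, which was 0.0817 on recovered reads. In pair 1, 15 fell and 1 rose (15 and 1 adjusted over the list alone; adjusted p = 1.20e-07, and 0.245 with an estimated correlation). In pair 3, 2 fell (5 adjusted over the list alone; adjusted p = 0.00152, 0.446 with an estimated correlation, and 0.0776 without library B of 4N-3). The oxytocin receptor gene OXTR went from 0.621 ± 0.0772 to 8.23 ± 0.594 RPKM in pair 2 (2.96, SE 0.11). TIMP3, an inhibitor of matrix proteases, went from 0.00112 ± 0.000455 to 5.77 ± 1.05 (3.63, SE 0.09). G0S2, an inhibitor of lipolysis, went from 1.71 ± 0.249 to 32.4 ± 1.87 RPKM (3.90, SE 0.22). RHOB, a small GTPase gene, went from 22.8 ± 0.827 to 106 ± 4.52 (2.20, SE 0.09), and the actin crosslinker gene FLNC from 11.4 ± 0.458 to 38.6 ± 1.22 (1.71, SE 0.13). LUM fell by 3.38 (SE 0.14). CCL2 went from 23.2 ± 3.73 to 0.398 ± 0.153 RPKM (-4.72, SE 0.20), and the immediate early genes EGR1 and FOS fell by 3.39 (SE 0.24) and 2.69 (SE 0.32). In all, 470 genes were called, 239 higher and 231 lower in 4N-2. At any fold 2085 rose and 1556 fell. On recovered reads 1608 were called higher and 1902 lower. CADM1, an adhesion molecule gene, was at 0 reads in 2N-2 against 11743 in 4N-2, at least 4730-fold higher. The red cell glycophorin gene GYPC had 3 reads against 3569, a ratio of 1438 (492 to 6975). The membrane protein gene PTGFRN went from 129 ± 8.29 to 0.0803 ± 0.0262 reads per M.

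Cell-cycle groups went the other way in pair 2 than in pair 1. Of the 31 mitosis genes 18 rose and none fell in 4N-2 (22 adjusted over the list alone, median 0.46; adjusted p = 7.31e-04, and 0.672 with an estimated correlation), with AURKB at 0.83 (SE 0.21), FOXM1 at 0.64 (SE 0.14) and KIF20A at 0.46 (SE 0.13). Of the 25 S phase genes 12 rose (12 adjusted over the list alone, median 0.38). Their call, at adjusted p = 0.0344, was at adjusted p = 0.781 with an estimated correlation, and at 0.0585, 0.101, 0.146 and 0.0916 without libraries A of 2N-2, B of 2N-2, C of 4N-2 and A of 2N-3. The difference of the 2 pairs passed for the mitosis and S phase groups (adjusted p = 6.24e-16 and 2.60e-08), at adjusted p = 0.234 and 0.402 with an estimated correlation. Of 9 centrosome genes 7 rose (8 adjusted over the list alone; adjusted p = 0.00279, and 0.330 with an estimated correlation), such as the centrin gene CETN2 at 0.87 (SE 0.12). Of 22 matrix genes 15 fell and 3 rose (16 and 3 adjusted over the list alone; adjusted p = 0.00114, and 0.489 with an estimated correlation). Of 27 lysosome genes 15 fell and 4 rose (16 and 5 adjusted over the list alone; adjusted p = 0.00152, and 0.571 with an estimated correlation), such as the protease gene CTSD, which went from 325 ± 37.0 to 131 ± 12.1 RPKM. Of 18 genes of the unfolded protein response 7 fell and 2 rose (8 and 2 adjusted over the list alone; adjusted p = 0.00719, and 0.434 with an estimated correlation).

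Pair 3 had the fewest called genes, 32, of which 14 were higher and 18 lower in 4N-3. EGR1 went from 14.3 ± 1.48 to 0.698 ± 0.295 RPKM (-3.65, SE 0.24, adjusted p = 1.17e-06) and FOS from 5.41 ± 2.51 to 0.322 ± 0.286 (-2.81, SE 0.32, adjusted p = 1.35e-04). JUNB, of the same early response, fell by 1.31 (SE 0.21), the Notch target HES1 by 1.12 (SE 0.16), the galectin gene LGALS3 by 1.24 (SE 0.10) and CCL2 by 1.36 (SE 0.20). POSTN, which encodes the matrix protein periostin, went from 0.193 ± 0.0396 to 1.52 ± 0.0729 RPKM (1.54, SE 0.06), and IL1B went from 4.53 ± 0.470 to 10.7 ± 0.0918 (1.16, SE 0.10). LUM rose by 1.01 (SE 0.14), KCTD12 by 1.11 (SE 0.10) and the integrin gene ITGA2 by 1.03 (SE 0.16). KRT81 fell by 1.30 (SE 0.17). At any fold 193 genes rose and 137 fell. On recovered reads 250 were called higher and 339 lower, among them NUP210 (30.2 ± 7.53 to 0.196 ± 0.0518 reads per M) and GPR143 (28.4 ± 5.05 to 0.0746 ± 0.0677). RIN3, a regulator of small GTPases, was at 0 reads in 4N-3 and at least 385-fold lower. The matrix proteoglycan gene BGN fell by 4.65 (SE 0.35) and the glutamate receptor gene GRIK5 by 4.60 (SE 0.23). GRIK5 rose by 3.34 (SE 0.11) in pair 2. Some of these calls rested on single libraries: KCTD12 fell below 2-fold without library A of 2N-3 (0.98), ITGA2 without that library (0.77) or C of 4N-3 (0.97). LUM fell below 2-fold without C of 2N-3 (0.98) or C of 4N-3 (0.77), and KRT81 without both doubted libraries (-0.95). The count of 32 became 55 without library C of 2N-3, and 2 when the 6 libraries of the pair were fitted alone. In the fit of all 18 libraries the wider spread of pair 3 counts only in part. The SE and adjusted p of pair 3 may thus be too small, also where a call in all 3 pairs rests on them.

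Of the 22 matrix genes tested on RPKM 9 rose and none fell in pair 3 (11 adjusted over the list alone, median 0.30; adjusted p = 1.24e-08, and 0.261 with an estimated correlation). No mitosis gene, S phase gene or centrosome gene rose or fell, over all genes or adjusted over the list alone, and these groups did not pass (adjusted p = 0.237, 0.50 and 0.452). Without library C of 4N-3, the library with low levels of these genes, the mitosis group (adjusted p = 3.68e-06, and 0.399 with an estimated correlation) and the S phase group (adjusted p = 1.20e-05, and 0.456 with an estimated correlation) passed as higher in 4N-3. Of 38 ribosomal protein genes none rose or fell, over all genes or adjusted over the list alone. The group was lower in 4N-3 at adjusted p = 2.02e-06, which was adjusted p = 0.670 with an estimated correlation and 0.682 without library A of 2N-3. RPS27, the member with the widest spread named, lay at 217 ± 98.5 RPKM in 2N-3 and at 143 ± 5.65 in 4N-3. Of 18 glycolysis genes 1 rose and 1 fell (1 and 3 adjusted over the list alone; adjusted p = 0.0185, 0.661 with an estimated correlation, 0.166 without library A of 2N-3 and 0.0879 without C of 4N-3). Of 25 actin and adhesion genes 1 rose and 1 fell (11 and 2 adjusted over the list alone; adjusted p = 0.0214, 0.436 with an estimated correlation, 0.0600 without library A of 2N-3 and 0.0544 without A of 4N-3). Of 8 genes of the epithelial-mesenchymal list 2 rose and 1 fell (5 and 1 adjusted over the list alone; adjusted p = 0.0235, 0.212 with an estimated correlation and 0.0586 without library C of 2N-3). Of the 10 secreted factors 1 rose and 1 fell (3 and 1 adjusted over the list alone), at adjusted p = 0.0498 and, with an estimated correlation, adjusted p = 0.245. That call was lost without any 1 of 12 libraries (A, B or C of 4N-1, A, B or C of 2N-2, B of 4N-2, A, B or C of 2N-3, A or C of 4N-3), at adjusted p = 0.0520 to 0.138.

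**Figure D3:**
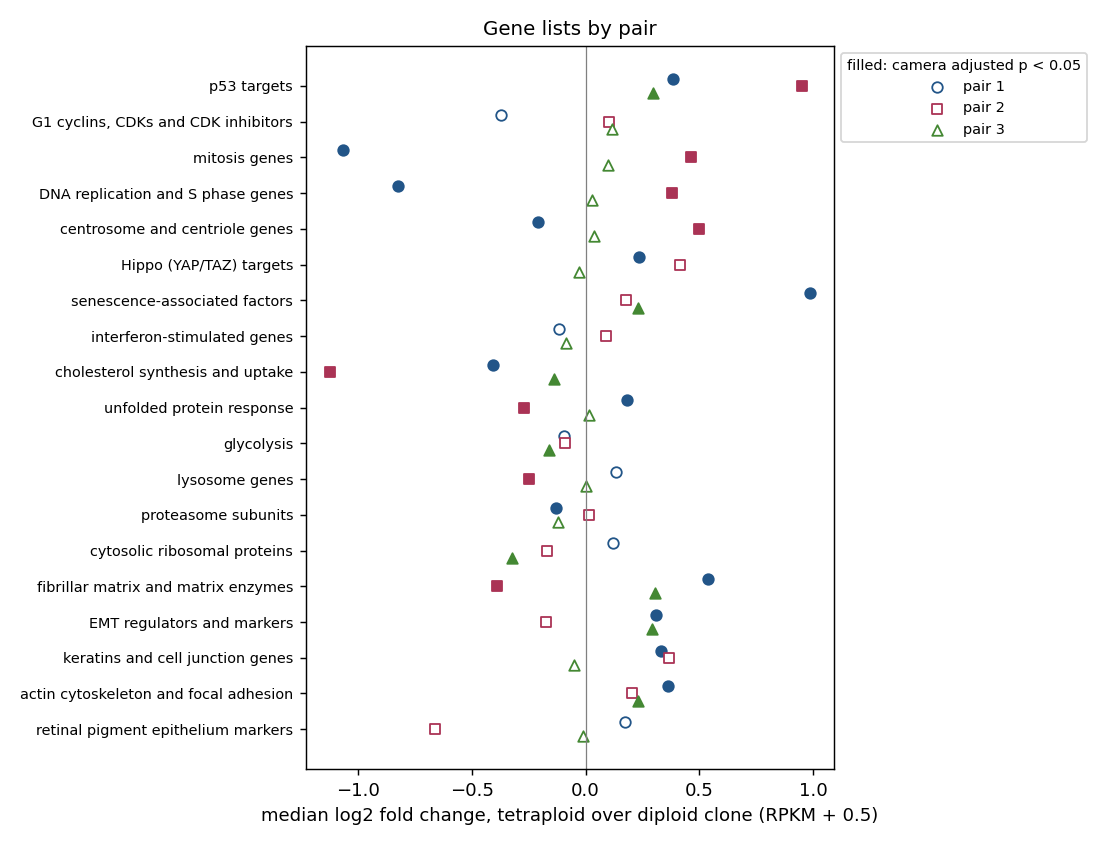
Median log2 change (4N over 2N) of the tested members of each gene list in the 3 pairs; filled marks passed camera with the preset correlation. The p53 targets lie above 0 in every pair (0.38, 0.95 and 0.30), and the mitosis genes lie at -1.06, 0.46 and 0.10.

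The lists not yet described gave no call in a given pair unless a value says so. In pair 1 the 13 interferon-stimulated genes had 5 that fell (5 adjusted over the list alone; adjusted p = 0.0705), such as IFI44 at -0.29, and without library C of 2N-1 the group passed (adjusted p = 0.0328, and 0.261 with an estimated correlation). In pairs 2 and 3, 2 rose and 3 fell (the same over the list alone; adjusted p = 0.689, median 0.09, mean -0.04) and 1 fell (1 rose and 2 fell over the list alone; adjusted p = 0.612). The 30 proteasome genes were lower in pair 1 with 1 that fell (none over the list alone; adjusted p = 0.0144, and 0.781 with an estimated correlation). In pair 2 they had 1 that rose, PSMD2 (0.72, SE 0.13), and 2 that fell (the same over the list alone; adjusted p = 0.819). In pair 3 none rose or fell (none over the list alone; adjusted p = 0.0579). There the group passed as lower without B of 2N-3 (adjusted p = 0.00226), C of 2N-3 (0.0251), A of 4N-3 (0.0234) or B of 4N-3 (0.0188), which was 0.746 to 0.782 with an estimated correlation. In pair 2 the median of the proteasome genes (0.01) and mean (0.02) lay above 0 and the direction of the test was down. Ribosomal protein genes had none that rose or fell in pair 1 (adjusted p = 0.138) and 1 that fell in pair 2, RPLP0 (-0.54, SE 0.16; none over the list alone; adjusted p = 0.0812). Without library A of 2N-3 the ribosomal group passed in pair 1 as higher (adjusted p = 0.00110) and in pair 2 as lower (adjusted p = 0.00164), both at 0.725 with an estimated correlation. In pair 2 it also passed without C of 4N-2 (adjusted p = 0.0455, and 0.820 with an estimated correlation). Glycolysis genes had 2 that fell in pair 1, such as ENO1 (-0.53, SE 0.13; 2 over the list alone; adjusted p = 0.105), and 1 that rose and 3 that fell in pair 2 (the same over the list alone; adjusted p = 0.178). Lysosome genes had 4 that rose and 1 that fell in pair 1 (6 and 1 over the list alone; adjusted p = 0.0727). They had 1 that fell in pair 3 (2 over the list alone; adjusted p = 0.390, and without library C of 4N-3 0.0279, or 0.626 with an estimated correlation), with a median of 3.44e-04 and a mean of -0.08.

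Hippo targets had 8 that rose and 5 that fell in pair 2 (10 and 5 over the list alone; adjusted p = 0.0754). They had 3 that fell in pair 3 (1 rose and 3 fell over the list alone; adjusted p = 0.227, and without library A of 2N-3 0.00164, or 0.513 with an estimated correlation). Secreted factors had 5 that rose and 3 that fell in pair 2 (the same over the list alone; adjusted p = 0.819), with a median of 0.18 and a mean of -0.22. Genes of the unfolded protein response had 1 that rose in pair 3 (1 over the list alone; adjusted p = 0.10, and as higher without library A of 2N-3 0.00110, or 0.408 with an estimated correlation). The epithelial-mesenchymal list had 3 that rose and 3 that fell in pair 2 (3 and 4 over the list alone; adjusted p = 0.645), with a median of -0.17 and a mean of 0.06. Keratin and junction genes had 5 that rose in pair 2 (5 over the list alone; adjusted p = 0.170) and 1 that rose and 1 that fell in pair 3 (the same over the list alone; adjusted p = 0.699). Actin and adhesion genes had 10 that rose and 5 that fell in pair 2 (11 and 5 over the list alone; adjusted p = 0.0727). Of 3 tested markers of retinal pigment epithelium 1 rose in pair 1, 1 rose and 2 fell in pair 2 and none changed in pair 3, with the same counts adjusted over the list alone (adjusted p = 0.586, 0.699 and 0.819). Of these, RDH5, a visual cycle enzyme gene, went from 5.88 ± 0.317 to 28.7 ± 1.37 RPKM in pair 2 and the transcription factor gene OTX2 fell by 0.66 (SE 0.13). The median of the list there was -0.66 and the mean 0.26, and in pair 3 they were -0.01 and 0.02. Of 24 markers of other cell types only CD68, a lysosomal protein of macrophages, could be tested on RPKM; it fell by 0.71 (SE 0.09) in pair 1 and rose by 1.46 (SE 0.09) in pair 2. On recovered reads 8 markers could be tested, of which 1 fell in pair 1, 3 rose in pair 2 and none changed in pair 3, with the same counts adjusted over the list alone (adjusted p = 0.479, 0.276 and 0.489). Over all lists and comparisons 41 of 76 tests passed with the preset correlation and 6 with an estimated one: the p53 targets in each pair, the secreted factors and the epithelial-mesenchymal list in pair 1, and the cholesterol genes in pair 2. On recovered reads 39 of 80 passed and 4 with an estimated correlation, the p53 targets in each pair and the secreted factors in pair 1. Calls lost on reads were those of the epithelial-mesenchymal list in pairs 1 and 3 (adjusted p = 0.109 and 0.529), the unfolded protein response in pair 2 (0.119), the secreted factors in pair 3 (0.905) and the matrix genes across clones (0.944). Calls made only on reads were those of the G1 list in pair 3 (adjusted p = 0.0464, and 0.238 with an estimated correlation), the actin and adhesion genes in pair 2 (0.0235, and 0.568) and the proteasome genes in pair 3 (0.0277, and 0.698). More members could be tested on reads, and some counts differed with them. Of 31 matrix genes 15 rose and 3 fell in pair 1 (19 and 3 adjusted over the list alone), and 10 rose and 4 fell in pair 3 (12 and 4). Of 29 interferon-stimulated genes 4 rose and 10 fell in pair 2 (4 and 10 adjusted over the list alone, median -0.04), and of 12 retinal pigment epithelium markers 3 rose and 6 fell there (3 and 6).

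Changes that recurred in all 3 pairs were few on RPKM and more on reads. PLAT, which encodes tissue plasminogen activator (ENSG00000104368, chromosome 8, 42175233 to 42207724), went from 3.58 ± 0.184 to 9.56 ± 0.0806 RPKM (1.30, SE 0.12). It went from 5.39 ± 0.959 to 23.8 ± 2.51 (2.05, SE 0.12) and from 2.99 ± 0.219 to 8.73 ± 1.17 (1.40, SE 0.12). On recovered reads MBNL3, which encodes a splicing regulator of the muscleblind family, rose by 6.87 (SE 0.47) and 6.54 (SE 0.46) in pairs 1 and 2, and in pair 3 had 2 reads against 1033, a ratio of 511 (141 to 4223). HOXA3, a gene of the HOXA cluster of body-axis regulators, fell by 5.42 (SE 0.34), 6.76 (SE 0.36) and 6.04 (SE 0.39), from levels of 5.08 ± 0.567, 10.3 ± 0.376 and 4.93 ± 0.619 reads per M. Its neighbour HOXA2 was at 0 reads in each tetraploid clone and at least 9.91-fold, 36.1-fold and 9.77-fold lower than in the diploid partner. The homeobox gene DLX6 fell by 3.02 (SE 0.18), 2.69 (SE 0.19) and 2.81 (SE 0.18), the secreted glycoprotein gene CHI3L1 by 4.02, 3.32 and 2.82, and ESRP1, an epithelial splicing regulator gene, by 2.86, 4.48 and 2.21. MAP10 was at 0 reads in each tetraploid clone and at least 48.1-fold, 12.4-fold and 53.9-fold lower. BEND4 was at least 20.9-fold and 40.8-fold lower in pairs 1 and 3, where the tetraploid clones had 0 reads, and fell by 6.92 (SE 0.60) in pair 2. The drug efflux pump gene ABCB1 rose by 4.31 (SE 0.35), 3.33 (SE 0.49) and 5.29 (SE 0.40).

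On RPKM, 4 genes were called higher in all 3 pairs and none lower, against 0.00224 expected if the pair lists were independent. Beside PLAT these were AC119751.4 and the genes ENSG00000225015 and ENSG00000233218, which the annotation at hand lacks. ENSG00000225015 rose by 2.25, 2.80 and 1.40, ENSG00000233218 by 2.59, 1.83 and 1.10 and AC119751.4 by 1.88, 2.62 and 1.09. The pair 3 call of AC119751.4 (adjusted p = 0.0386) ended without any 1 of 12 libraries (A, B or C of 2N-1, A of 4N-1, A or B of 2N-2, A or B of 4N-2, A or B of 2N-3, A or C of 4N-3), with changes of 0.75 to 1.18. That of ENSG00000233218 (1.10) fell just below 2-fold without library B of 2N-3, where 2 genes were called in all 3 pairs. On recovered reads, 59 genes were called higher and 40 lower in all 3 pairs, against 0.394 and 0.739 expected from independent lists. Opposite calls were shared in excess too: 143 rose in pair 1 and fell in pair 2, against 43.7 expected. Libraries B and C of 4N-3 differed 8-fold or more from 4N-1 on 12 genes and from 2N-3 on 38. Those of 4N-1 differed so from 4N-3 on 15 and from 2N-1 on 46. The tetraploid clones of pairs 1 and 3 were thus alike, and the excess over independent lists does not measure recurrence with ploidy alone. Of the 59, 28 (47.5%, against 8.27% of all genes tested on reads) had a mean under 10 reads per library over the diploid clones. Of the 40, 21 had a mean under 10 reads per library over the tetraploid clones. Some of the genes called in all 3 pairs may count the same reads under several identifiers. SLCO1B3 and AC011604.2 each rose by 4.27, 3.27 and 6.71. The number of separate changes was not worked out, so the counts of 59 and 40 may be too high.

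Across clones, where each clone counts once and the pair is a block, PLAT was 1.58 higher in the tetraploid clones (SE 0.19, adjusted p = 0.857) and CDKN1A 1.32 higher (SE 0.20, adjusted p = 0.857). On recovered reads HOXA3 was at -6.12 (SE 0.35, adjusted p = 0.127) and CCND2 at 7.20 (SE 1.10, adjusted p = 0.505). With limma no gene was called across clones, and 391 of 9704 passed an unadjusted p of 0.05. With limma-voom on recovered reads the count was also 0, with 1075 of 23396 at an unadjusted p of 0.05. Both numbers are below the share of 0.05 that tests without any change would give, so there was no excess of small p-values. No member of any list rose or fell over all genes. Adjusted over the list alone, 12 p53 targets and 1 G1 gene rose and 2 cholesterol genes fell. The p53 targets passed as a group, as higher (median 0.51, adjusted p = 6.13e-23, and 0.330 with an estimated correlation), as did the actin and adhesion genes (median 0.26, adjusted p = 3.75e-06, and 0.30 with an estimated correlation). The cholesterol genes passed as lower (median -0.55, adjusted p = 1.40e-15, and 0.425 with an estimated correlation). The secreted factors (0.30, adjusted p = 7.43e-04) and the glycolysis genes (-0.12, adjusted p = 0.0224) also passed, at adjusted p = 0.299 and 0.382 with an estimated correlation. A further 7 groups passed with the preset correlation and lost the call without 1 library. The mitosis genes (-0.19, adjusted p = 0.00892, and 0.781 with an estimated correlation) were at 0.0735 without library C of 4N-3. The S phase genes (-0.15, adjusted p = 0.0185, and 0.781 with an estimated correlation) were at 0.279 without that library and 0.0713 without C of 2N-2. Without library A of 2N-3 the Hippo targets (0.25, adjusted p = 0.00719, and 0.425 with an estimated correlation) were at 0.0726 and the proteasome genes (-0.09, adjusted p = 0.0144, and 0.720 with an estimated correlation) at 0.182. Without the same library the ribosomal proteins (-0.12, adjusted p = 0.00719, and 0.781 with an estimated correlation) were at 0.695 and the matrix genes (0.15, adjusted p = 0.00719, and 0.672 with an estimated correlation) at 0.106. The keratin and junction genes (0.19, adjusted p = 0.0475, and 0.489 with an estimated correlation) lost the call without any 1 of 7 libraries (C of 4N-1, C of 2N-2, A or B of 4N-2, A or C of 2N-3, C of 4N-3), at 0.0579 to 0.0860. The other lists tested did not pass across clones: the epithelial-mesenchymal list (0.0907), the interferon-stimulated genes (0.285), the centrosome genes (0.362), the lysosome genes (0.170), the unfolded protein response (0.779) and the retinal pigment epithelium markers (0.671).

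The size or direction of the change differed between pairs for 1023 genes, by a moderated F test with a difference of 2-fold or more, and for 5206 genes on recovered reads. Among the widest differences on log2(RPKM + 0.5), where the pseudocount narrows those of genes near 0 such as TIMP3, were those of CCL2 (6.25), G0S2 (5.54), LUM (5.52), EGR1 (4.63), TIMP3 (3.65), FOS (3.62) and OXTR (3.57), as the span between the highest and the lowest of the 3 log2 changes. LUM rose in pairs 1 and 3 and fell in pair 2, and G0S2 rose in pair 2 and fell in pairs 1 and 3. AURKB fell in pair 1 and rose in pair 2, and the F test of any difference among the 3 pairs passed at adjusted p = 3.29e-04. For CDKN1A (adjusted p = 0.00129) and PLAT (adjusted p = 0.00431) the changes also differed between pairs, by 0.76 and 0.75. Those of HOXA3, MBNL3 and DLX6 were not shown to differ (adjusted p = 0.0937, 0.10 and 0.539). On recovered reads pairs 1 and 2 shared more calls than independent lists would give, both in the same direction (162 rose against 36.9 expected, 99 fell against 51.0) and in opposite ones. Of the latter, 143 rose in pair 1 and fell in pair 2, against 43.7 expected, and 110 fell in pair 1 and rose in pair 2, against 43.1. Between pairs 1 and 3, 24 rose in the first and fell in the other, against 7.78, and 2 fell in the first and rose in the other, fewer than the 6.70 expected. Between pairs 2 and 3 these were 88 against 23.3 and 63 against 20.3. In the same direction pairs 1 and 3 shared 129 that rose, against 5.74 expected, and 110 that fell, against 9.09. Pairs 2 and 3 shared 98 that rose, against 17.2, and 110 that fell, against 27.6.

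Genes of chromosome 1 were lower as a set in 4N-2. The median log2 change of its 945 tested genes in pair 2 lay -0.24 from that of the other genes (camera, adjusted p = 2.44e-08, and 0.279 with an estimated correlation). On recovered reads the value was -0.26 over 2154 genes (adjusted p = 1.97e-04, and 9.55e-09 with an estimated correlation). Against the mean of the other 5 clones, 4N-2 lay at -0.335 ± 0.00431 (SD, n = 3 libraries) over 1170 well-read genes, of which 79.4% were below the rest. All 29 windows of 40 genes along the chromosome were lower in 4N-2, at -0.47 to -0.13 from the mean of the 6 clones. Loss of 1 of 4 copies in every cell of 4N-2, with expression in proportion to copies, would give -0.42 from the other 5 clones and -0.35 from the mean of the 6. Chromosomes 12 (0.109 over 575 genes, adjusted p = 8.17e-05, and 0.279 with an estimated correlation) and 19 (-0.104 over 624 genes, adjusted p = 0.00151, and 0.997 with an estimated correlation) also passed in pair 3. On recovered reads their offsets were 0.107 (adjusted p = 0.0115, and 0.00113 with an estimated correlation) and -0.110 (adjusted p = 0.0128, and 0.967 with an estimated correlation). Without library A of 2N-3 chromosome 12 was at 0.0750, under the minimum of 0.1, but still at adjusted p = 2.55e-06. Against the mean of the 6 clones its genes lay lower in each library of 2N-3 (-0.132, -0.0726 and -0.0675), with means of 0.0110 to 0.0259 in the other clones. Without the same library chromosome 19 was at -0.00955 (adjusted p = 0.815). With median-of-ratios scaling (-0.0962) or a mean of 5 RPKM or more (-0.0938) the call of chromosome 19 also ended, and those of chromosomes 1 and 12 did not. Its offset was also under the minimum without B of 4N-3 (-0.0972) and without C of 4N-3 (-0.0926).

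**Figure D4:**
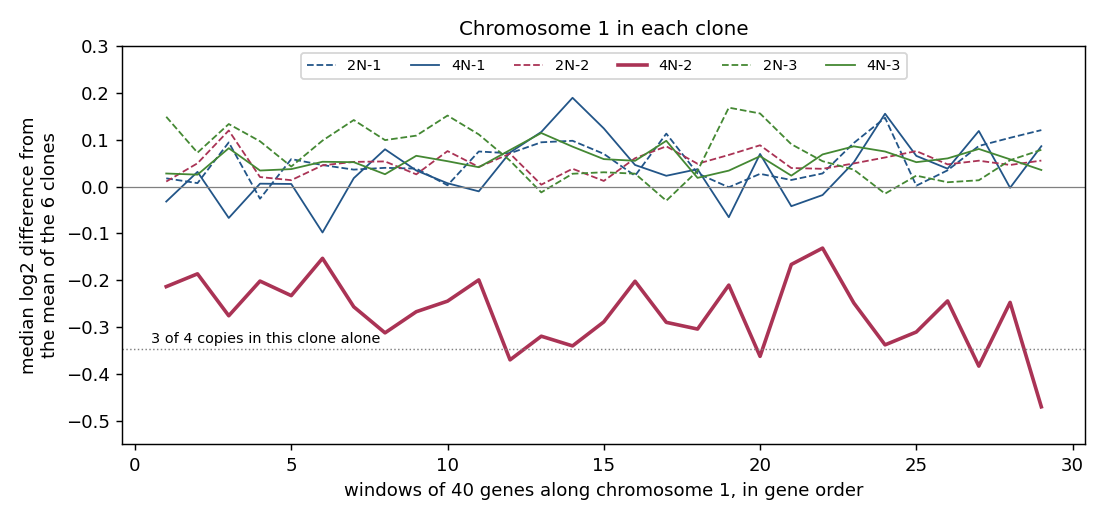
Median log2 difference from the mean of the 6 clones in 29 windows of 40 genes along chromosome 1, 1 line per clone; the dotted line, at -0.35, marks 3 of 4 copies in 1 clone alone. All windows of 4N-2 lie at -0.47 to -0.13, and the lowest window of another clone lies at -0.0981.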

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

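Of the tests in this part, those of the corrected chromosome 1 offset, of a wrong label and of mixed RNA were planned before their results were seen, and those of scaling, of windows, of copy number, of transcript length, of depth and of cycling cells were chosen after.

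Changes that differed between the pairs stood out most, with 1023 genes past the F test on RPKM and 5206 on recovered reads. As the span of the 3 log2 changes, the immediate early and inflammatory genes had 6.25 (CCL2), 4.63 (EGR1), 3.62 (FOS), 3.12 (FOSB), 1.51 (JUNB) and 1.21 (IL1B), with 3.31 for HES1 and 1.09 for LGALS3 on reads. Contractile and matrix genes had 5.52 (LUM), 3.65 (TIMP3), 3.74 (BGN, on reads), 2.86 (MYL9), 1.90 (POSTN), 1.5 (TAGLN) and 1.36 (ACTA2), and ANKRD1 had 2.10, RHOB 2.60, FLNC 1.93 and KRT81 1.15. Cell-cycle genes had 2.08 (AURKB), 1.94 (FOXM1), 1.86 (KIF20A), 1.85 (MKI67), 1.66 (PLK1), 1.21 (CCNB1) and 1.03 (MCM7), and the p53 targets had 2.66 (SPATA18, on reads), 1.83 (BTG2) and 1.24 (AEN). Genes of lipid metabolism and lysosomes had 5.54 (G0S2), 3.18 (SCD), 2.15 (HMGCS1), 2.04 (INSIG1), 2.17 (CD68) and 1.73 (CTSD), and receptor and membrane genes 3.57 (OXTR), 2.54 (PTGFRN) and 1.42 (PCDHB5). Other genes on RPKM had 2.03 (HSPB7), 1.97 (RDH5), 1.31 (KCTD12), 1.21 (MAGEH1), 1.08 (PSMD2), 1.02 (XBP1), 1.53 (AC119751.4), 1.49 (ENSG00000233218) and 1.41 (ENSG00000225015). On recovered reads, where fitted values of a clone near 0 reads depend on the prior count, CCND2 had 5.51, CCND2-AS1 3.95, CADM1 13.6, GPR143 11.5, RIN3 10.2, SLC2A10 8.62, NUP210 8.57, GYPC 8.49, GRIK5 7.94, ESRP1 2.27, MAP10 2.11, ABCB1 1.97 and HOXA2 1.86.

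Between pairs, 14 lists differed with the preset correlation, here as the widest difference of medians among the comparisons that passed. Pair 2 minus pair 1 gave 1.53 for mitosis genes, 1.20 for S phase genes, 0.70 for centrosome genes, -0.93 for matrix genes, -0.81 for secreted factors, -0.48 for the epithelial-mesenchymal list, -0.45 for the unfolded protein response and -0.38 for lysosome genes. Pair 3 minus pair 2 gave 0.98 for cholesterol genes, -0.66 for p53 targets and -0.44 for Hippo targets, and pair 3 minus pair 1 gave -0.44 for ribosomal proteins, -0.38 for keratins and -0.13 for actin and adhesion genes. With an estimated correlation 1 of these differences passed, that of the p53 targets (adjusted p = 0.0222). The offset of chromosome 1 differed between pairs 3 and 2 by 0.25.

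Genes of chromosome 1 were lower in 4N-2 than in the other 5 clones in each of its 3 libraries. After correction for GC content, transcript length and span the highest offset of the 3 libraries was -0.3344, and a scaling of the libraries does not account for it, since the offset from the other chromosomes, which no scaling moves, was at most -0.3313. All 29 windows lay below -0.1 from the mean of the 6 clones, which argues against a stretch or a few genes, and the lowest library, at -0.3394, stayed above the -0.42 from the other 5 clones that loss of 1 of 4 copies in every cell would give if expression followed copies. Loss of 1 copy in about 82.8% of the cells of 4N-2 would give the mean offset of -0.335 from the other 5 clones. Loss in every cell, with expression that changes less than copies, could give it too, and these were not tested apart. The share depends on the genes and the reference. Against 2N-2 alone, on recovered reads of 2154 genes, the offset was -0.263, which would give a smaller share. Simulated offsets of -0.4 came out at -0.333 in the fit on RPKM and at -0.402 on reads, so that the RPKM fit is not a measure of copy number.

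Library A of 2N-3 lay apart from libraries B and C of its clone. Its deviation followed transcript length across genes (Spearman correlation -0.6507 across genes, which are not independent, against at most 0.3413 in size in the 15 libraries of the other clones), so a difference in RNA quality or library preparation may account for part of it. The trend with length, GC content and span is not the whole, since the SD over genes after correction was 0.4389, above the 0.317 of any other clone's library. The tables argue against low depth, as the lowest other library had 0.992 times its reads in genes, and against a sample of another clone, as at least 99.21% of the genes that differ 8-fold or more between clones lay nearer its own. No biological explanation was tested, since the design gives no group for a single library.

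Library C of 4N-3 lay apart from A and B in the direction of 4N-1. At -9.09 on the first principal component it did not reach 4N-1 (-17.5 to -16.0). Libraries of 2N-1 and 2N-2 (-9.64 to -3.71) lay nearer there. Of 16 genes that differ 8-fold or more between 4N-3 and 4N-1, library C lay nearer 4N-3 on 14 (87.5%, interval 61.7% to 98.4%). This missed the limit of over 90% set before the test but lies well above the share under 50% that a sample of another clone would give. Against 2N-2 it was 51 of 53 genes and against 2N-1 43 of 44. A mixture with RNA of 4N-1 would have needed a share of 55.8% to give the mitosis genes their levels. The 5 genes read in 4N-1 and low in A and B reached a median of 2.935% of its level. Mixtures with other clones were not tested. Mitosis and S phase genes lay lower than in A and B by a median of -0.7643 (67 of 67 genes), beyond the -0.261 of any library of another clone, so fewer cycling cells in that culture may account for it, as a hypothesis found and tested on the same data. Whether growth to a higher density or handling lay behind it was not tested.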

How the results depend on the processing

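Tests on recovered reads and tests without the doubted libraries A of 2N-3 and C of 4N-3 were chosen after seeing the data; the others were planned. Counts are of pairs 1, 2 and 3, all 3 pairs, and differences between pairs, which were 141, 470, 32, 4 and 1023. With a mean of 5 RPKM or more they were 66, 163, 8, 1 and 366, where fewer genes were tested, and with no minimum fold 2027, 3641, 330, 80 and 3780. A pseudocount of 0.1 gave 271, 707, 58 and 10 for the first 4, and a pseudocount of 1 gave 78, 312, 20 and 2, since it shrinks changes at low levels. Recovered reads gave 1164, 3510, 589, 99 and 5206, without library A of 2N-3 1253, 3589, 523, 96 and 5235, and without both doubted libraries 1288, 3627, 671, 103 and 5632, where more genes were tested. Of the calls on RPKM, 135, 451, 29 and 4 were also made on reads. With only their own 6 libraries the pairs had 141, 474 and 2 called genes. Replicates lay furthest apart in pair 3. There the chi-square per gene was 151 between A and B of 2N-3 and 42.2 between B and C of 4N-3. In pairs 1 and 2 it was at most 23.2 (A and C of 4N-2). The estimate shared by 18 libraries takes in this spread only in part, so tests of pair 3 on it may be too lenient. Whether that alone accounts for the fall to 2 was not tested. With libraries of the same pair and letter as a block, reads gave 1112, 3424, 527, 91 and 4936; on RPKM the block moved no count by over 1.5 times (138, 466, 26, 4 and 1003).

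Across clones the count of 0 became 26 with 18 libraries and the correlation within a clone, 25 with the replicate block and libraries as independent, 2 without pair 1, 18 without pair 2 and 0 without pair 3; the cause was not tested. Lists called went from 41 to 6 with an estimated correlation, and chromosomes on RPKM from 3 to 0; on reads chromosome 1 of pair 2 (adjusted p = 9.55e-09) and chromosome 12 of pair 3 (0.00113) still passed. Chromosomes called were 1 without both doubted libraries, and 1 on reads without library A of 2N-3 or both, with chromosome 1 of pair 2 left. With single libraries left out, counts were 117 to 169, 446 to 492, 27 to 55, 2 to 5 and 927 to 1172, 0 across clones, 34 to 42 lists and 1 to 3 chromosomes. The extremes that moved a count by over 1.5 times were library C of 2N-3 (55 in pair 3), B of 2N-3 (2 in all 3 pairs) and A of 2N-3 (1 chromosome). Median-of-ratios scaling, quantile normalization and no filter moved no count by over 1.5 times. Of the single values of named genes, 633 in all, no direction turned where a call was made. Over all alternatives 16111 values stayed on their side of the threshold, 178 passed it newly and 304 lost it. Of the 16111, 11282 came from leaving out 1 library. Of the 304, 174 came with no filter, where 459 stayed. At 37.1 M reads in genes or more per library, genes of a few reads give wide intervals, and no fold can be given where both clones are at or under 3 reads.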

Other observations

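The test of neighbouring genes and the tests on other splits of the samples were chosen after the results were seen.

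Genes called in all 3 pairs on recovered reads lay close together in the order of tested genes more often than random sets of them. Of 90 such genes placed on a chromosome, 21 had another called gene, changed the same way and not overlapping, within 5 tested genes on either side, among them HOXA2, HOXA3 and EDA2R. The distance in bases was not limited. SPATA18 (from 52051331) also counted, but the other chromosome 4 genes among the 21, such as AC119751.4 (to 49580189) and SNX18P25, are annotated as pseudogenes. In 10000 random sets of the same size the mean was 1.64 and the highest 13 (one-sided permutation p = 1e-04, the smallest these sets can give), and outside chromosome 7, which holds the HOXA cluster, 15 genes had such a neighbour. A change that covers neighbouring genes is consistent with the 21, as a hypothesis; reads shared between related genes of a cluster may add to the number and were not tested apart.

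Other splits of the libraries bear on each count. For pairs 1, 2 and 3 the 10 splits of 6 libraries are too few for a share under 0.05; 1 of 10 was as large in each, the real one, with 141, 470 and 32 genes against at most 0, 0 and 6 in the others. The 6 in pair 3 came from the split that sets libraries A and B of 2N-3 and C of 4N-3 against the rest. For the 6 clones the 10 splits are also too few, the real count was 0, all 10 were as large, and the highest of the others was 113, from the split of 2N-1, 4N-1 and 2N-2 against the rest. With the pair as a block that split compares only 2N-2 with 4N-2, which points to a structure of the samples, the distance of 4N-2 from the others. For the 4 genes called in all 3 pairs 1 of 100 splits within pairs was as large and the others gave at most 0. Mixed libraries of pairs 1 and 2 gave no calls at all, which fixed that outcome, so these splits do not test agreement among the clones of the 3 pairs. For the 1023 genes that differed between pairs 1 of 100 splits was as large, and the others gave at most 748. A split other than the real one mixes libraries of 2 clones in a pair, which takes away differences between clones. The real split was thus set to give a large count, so these splits do not test chance among clones either. Few splits gave as many as the 41 lists (1 of 100, the others at most 40) and the 3 chromosomes (3 of 100, the others at most 3), but others came so close that these counts do not set single lists or chromosomes apart from chance.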
